A study of Homo sapiens with 4 samples.

How the data were processed

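RNA of A549 cells, a human lung adenocarcinoma line, was measured by RNA sequencing. Per the labels, cells were infected with shNT, taken here as a non-targeting control hairpin, or with shIno80, a short hairpin RNA against INO80, and total RNA was taken 4 days after infection. One label field speaks of transfection where the treatment protocol speaks of infection. Each group had 2 libraries. The number of different hairpins in shIno80 and their sequences are not given in the sources used here. Per the labels' protocols, libraries were made from purified total RNA with an Illumina TruSeq RNA library kit of the kind that selects polyadenylated RNA and does not record the strand.

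The deposited values were FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library) for RefSeq transcripts, per the deposited files, with 1 column per library and no pooling. The submitters' processing notes name TopHat2 2.0.4, Cufflinks 2.0.2 and the human genome build hg19, with no role or order given. The annotation release, the program options and any filter are not given in the sources used here. Each file listed 40723 transcripts. Transcript names were matched to gene symbols through an NCBI RefSeq gene table (assembly GRCh38.p14, used for names alone, so no coordinates are given), which named 39397 transcripts, and through the GENCODE release 29 identifier table, which named 494 more. The remaining 832 transcripts had no match and were left out of the gene tests. FPKM of the named transcripts were summed to 23191 genes, of which 7851 had more than 1 transcript. Because FPKM are scaled to transcript length, a gene's sum depends on how reads shared by its transcripts were divided among them.

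FPKM are not read counts, and the absolute depth of the libraries is unknown. Relative depth was read from transcripts under 0.1 FPKM that are the only transcript of their gene. In such transcripts the most frequent ratio between a pair of libraries is the ratio of what 1 fragment is worth. Relative to shNT replicate 1, the depth was 0.921 in shNT replicate 2, 1.02 in shIno80 replicate 1 and 0.944 in shIno80 replicate 2, from 261, 219 and 217 transcripts at the most frequent ratio among 1398, 1311 and 1291 compared, with a tolerance of 0.001 on the log2 scale. No interval for counting error can be given without counts. The precision of a value is known here from the spread between 2 libraries, shared across genes by the test. Reads of near-identical genes (histone clusters, ribosomal proteins and keratins with processed pseudogenes) and of overlapping or antisense genes cannot be told apart in these values.

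Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, 12211 in all. The test was limma 3.58.1 (lmFit, then eBayes with a trend in the variance) in R 4.3.3 on log2(FPKM + 1), shIno80 minus shNT, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every log2 fold given is on the log2(FPKM + 1) scale, which understates the change of genes of low expression. The main test had no block for the replicate number. The words rose, fell, higher and lower refer to genes past the threshold. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Gene lists were tested with limma's camera on the same model with a preset correlation between genes of 0.01, adjusted over the 31 lists with at least 5 tested members that were not markers of other cell types. Camera with an estimated correlation, camera on ranks, and fry, which asks whether the members of a list change and compares them with no other genes, were run beside it. The 39 lists held 1108 entries, of which 1085 were in the files under the same, an older or a newer symbol. The list of mitochondrially encoded genes had 0 members among the transcripts of the files.

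Before the data were examined, the test, the filter, the gene lists, the alternatives and the rule for named genes were fixed. The rule takes INO80, the subunits of its complex, the 12 genes with the largest log2 rise and the 12 with the largest fall among genes past the threshold whose libraries do not overlap between groups and whose higher group has a mean of at least 5 FPKM, and up to 4 members of each list by smallest p. Small nucleolar RNA, microRNA and other short RNA without a usual poly(A) tail were left out of these 24. Any other gene named was chosen after its values were seen, and this is said where it occurs. Some genes that the rule takes are not reported here. The alternatives were other pseudocounts (0.1 and 5 FPKM), other filters, median-ratio, upper-quartile and quantile scaling, a block for the replicate number, leaving out each library in turn, other variance models, keeping the transcript with the highest value of each gene, and a test against a fold of 1.5 (treat). Protein-coding genes alone, and genes without the sequence matches described below, were added after seeing the data.

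The 3′ UTR scan was chosen after the largest falls had been seen. Transcript sequences of GENCODE release 29 were available for 11807 tested genes (96.7%), and 10921 genes had a 3′ UTR of at least 50 nt. For each of the 15440 sequences of 7 bases found in the 3′ UTRs of at least 100 genes, the log2 folds of genes with and without it were compared after removing trends with 3′ UTR length, 3′ UTR GC content and transcript length, and the z was set against permutations of the genes. Because the scan uses presence alone, genes with 2 or more copies of a sequence were then compared with genes with 1 copy by a one-sided permutation test of the mean with 100000 draws, after removal of the same trends, with adjustment over the 2 sequences compared.

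Scripts were tested on simulated data for this comparison with 12031 genes. Of 55 genes changed by log2 0.5, 96.4% were recovered, and of 70 changed by log2 1 and 75 changed by log2 2, 100% were recovered. The changed genes were drawn from those of higher expression, so recovery near 1 FPKM was not tested. Of 11831 unchanged genes, 9 were called, which was 4.3% of the calls. The simulation without any change gave 1 called gene and 0 called lists. Genes were drawn independently of each other, so the simulation could not show false list calls from genes that vary together. The heptamer scan was tested on the 10921 genes with simulated values in which genes with a planted heptamer fell by log2 0.25, and it ranked 3 of 3 planted heptamers lowest. That fall was larger than the mean shifts of the sequences ranked lowest and highest below, -0.14 and 0.07 after removal of trends. No rise was planted. The lowest z with none planted was -3.59. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.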

Results

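INO80 is the ATPase of a chromatin remodelling complex that moves and edits nucleosomes at promoters, enhancers and replication forks. The comparison of shIno80 with shNT asks which transcripts of A549 lung cancer cells change 4 days after infection with the hairpin against it, with the transcription of oncogenes in view. Transcript levels were measured as FPKM in 4 libraries, 2 with shNT and 2 with shIno80. The libraries had 12061 and 12043 genes at 1 FPKM or more with shNT and 11915 and 11895 with shIno80. The 10 genes with the highest FPKM took 8.89% to 9.03% of the FPKM of a library. Depth relative to shNT replicate 1 was 0.921 in shNT replicate 2, 1.02 in shIno80 replicate 1 and 0.944 in shIno80 replicate 2. The correlation of log2 values across genes was 0.988 between the shNT libraries, 0.987 between the shIno80 libraries and 0.963 to 0.965 between libraries of different groups. Genes are not independent replicates in these correlations.

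INO80 fell from 7.13 ± 0.124 FPKM (SD, n = 2) with shNT to 1.26 ± 0.0311 FPKM (SD, n = 2) with shIno80. Its values were 7.04 and 7.22 FPKM in the shNT libraries and 1.24 and 1.28 FPKM in the shIno80 libraries, so the libraries followed their labels. The log2 fold was -1.85 (SE 0.0503, adjusted p = 2.56e-05), a 5.66-fold fall in FPKM. Of the 15 subunits of the INO80 complex, 8 rose, 3 fell and 4 did not pass the threshold. RUVBL1, an AAA+ ATPase that the complex shares with other remodellers, fell from 65.9 ± 2.58 to 40.0 ± 1.06 FPKM (log2 fold -0.70, SE 0.0481, adjusted p = 0.000156), whereas its partner RUVBL2 rose from 105.7 to 120.8 FPKM. The rises of the other subunits were small. INO80D rose from 1.48 to 2.38 FPKM (log2 fold 0.44), and NFRKB, TFPT, INO80B, MCRS1, ACTR8 and INO80E rose by log2 0.31, 0.29, 0.23, 0.23, 0.18 and 0.15. The actin-related subunit ACTR5 fell by 0.18 on the log2 scale. YY1, ACTL6A, UCHL5 and INO80C had log2 folds of 0.03, -0.05, -0.06 and -0.23 with adjusted p of 0.607, 0.432, 0.243 and 0.0722. The median log2 fold of the 15 subunits was 0.15 and the mean -0.07, and as a list they did not stand apart from other genes (adjusted p = 0.663). Several of these calls depended on single libraries or on the processing. ACTR5 had an adjusted p of 0.153 without shNT replicate 2 and 0.172 without shIno80 replicate 1. ACTR8 had 0.0975 without shNT replicate 1, 0.0665 without shIno80 replicate 1 and 0.065 without shIno80 replicate 2, and INO80E had 0.0687, 0.0888 and 0.113 in the same 3 cases. RUVBL2 had 0.109 and 0.0835 without shIno80 replicate 1 and replicate 2, and MCRS1 had 0.0635 without shIno80 replicate 2. INO80C passed the threshold without shNT replicate 1 (adjusted p = 0.0081), without shIno80 replicate 1 (adjusted p = 0.04997), under median-ratio scaling (adjusted p = 0.044) and with protein-coding genes alone (adjusted p = 0.00558), each time as lower. When the transcript with the highest value stood for each gene, NFRKB, ACTR5 and ACTR8 had adjusted p of 0.0742, 0.0822 and 0.0543, and UCHL5 passed as lower (log2 fold -0.19, adjusted p = 0.0244). With no filter on low values ACTR5 and ACTR8 had 0.0998 and 0.057, and with a minimum mean of 5 FPKM ACTR5 had 0.0615.

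**Figure D1:**
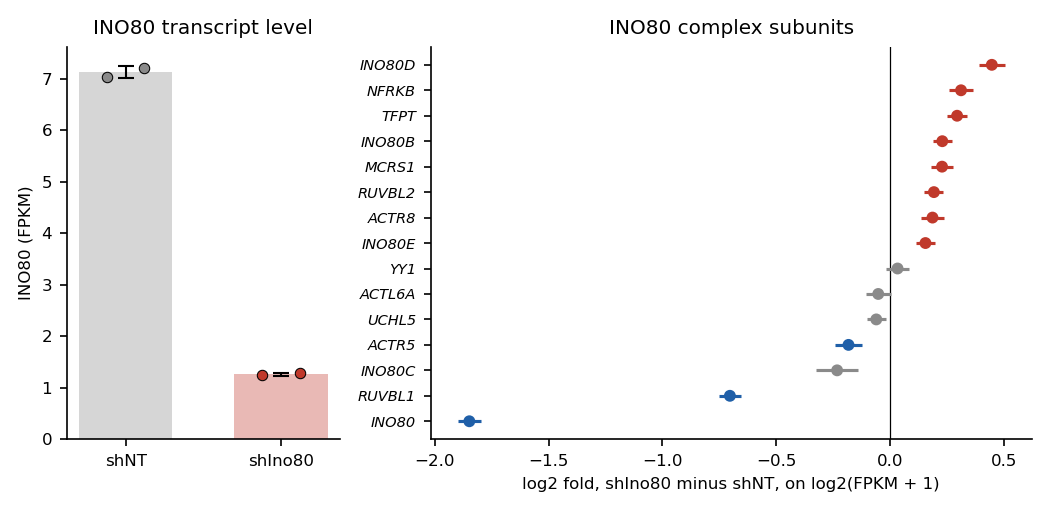
INO80 transcript level in FPKM in each library (points), with the group mean as a bar and the SD as the error bar, and the log2 fold, shIno80 minus shNT on log2(FPKM + 1), of 15 subunits of the INO80 complex with its standard error. Red points rose, blue points fell and grey points did not pass the adjusted p of 0.05. INO80 lies at 7.04 and 7.22 FPKM with shNT and at 1.24 and 1.28 FPKM with shIno80.

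Across the transcriptome, 4086 genes were higher and 3392 lower with shIno80 among 12211 tested, 61.2% in all. Most changes were small. The median size of the log2 fold among called genes was 0.34, and 78 genes were higher and 263 lower by log2 1 or more. A test against a fold of 1.5 left 124 genes higher and 388 lower, so large changes were more often falls. The values of the groups did not overlap in 82.1% of the tested genes, where chance gives 33.3%. The median log2 fold of all tested genes was 0.03. Median-ratio scaling turned the balance, with 3782 genes higher and 3859 lower.

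The largest rise by the rule for named genes was that of ANKRD1, a cardiac ankyrin repeat protein and known target of YAP, from 1.47 ± 0.112 to 13.0 ± 0.359 FPKM (log2 fold 2.51, SE 0.0552, adjusted p = 1.11e-05). KCNF1, a potassium channel subunit, rose from 3.03 to 16.2 FPKM, and SMPD1, the lysosomal acid sphingomyelinase, from 2.33 to 12.1 FPKM. FST, the activin antagonist follistatin, rose 5.02-fold to 12.5 FPKM. CHAC1, an enzyme that degrades glutathione, rose from 2.31 to 9.60 FPKM, and BBC3, the pro-apoptotic BH3 protein PUMA, from 3.90 to 13.3 FPKM. CTSL, the lysosomal protease cathepsin L, was the most abundant of the 12 and rose from 292 ± 16.1 to 868 ± 22.3 FPKM (log2 fold 1.57). EREG, a ligand of the EGF receptor, rose from 10.2 to 31.2 FPKM. DNAJB4, a co-chaperone, SLCO2B1, an organic anion transporter, GPAT3, an acyltransferase of triglyceride synthesis, and MATN2, a matrix protein, rose between 2.87-fold and 3.44-fold.

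The largest fall was that of CA9, a carbonic anhydrase induced in hypoxia, from 8.60 ± 1.80 to 0.26 ± 0.23 FPKM (log2 fold -2.93, SE 0.165, adjusted p = 9.06e-05). TM4SF4, a tetraspanin-like membrane protein, fell from 23.5 to 2.36 FPKM, and NTRK3, the receptor of neurotrophin-3, from 19.5 to 1.95 FPKM. PIR, an iron-binding nuclear protein encoded by a target gene of NRF2, fell from 57.3 ± 1.78 to 7.95 ± 0.000884 FPKM (log2 fold -2.70). FAM162A, a hypoxia-induced mitochondrial protein, fell from 45.3 to 7.95 FPKM, and PPT1, a lysosomal thioesterase, from 35.8 to 6.23 FPKM. HGD, an enzyme of tyrosine breakdown, fell 4.94-fold. BANF1, a DNA-binding protein of the nuclear envelope, fell from 150.4 ± 3.73 to 35.9 ± 0.768 FPKM. C12orf75, HDDC2 and DOK4 fell 4.403-fold, 4.43-fold and 3.90-fold in FPKM. INO80 itself ranked last of these 12 on the log2(FPKM + 1) scale, although its 5.66-fold fall in FPKM was larger than theirs. Of the 12 genes, FAM162A, BANF1 and HDDC2 had the octamer CCATTTCA in the 3′ UTR, and PIR, PPT1, C12orf75 and DOK4 had its first 7 bases, CCATTTC. Among the 12 largest rises, 0 genes had CCATTTC, and FST, EREG and DNAJB4 had CATTTCA alone. Another sequence described below, GAAGAGC, was in the 3′ UTR of FST, BBC3 and EREG among the rises and of PIR and INO80 among the falls. CHAC1 and NTRK3 had no 3′ UTR sequence to search. Across the 10921 genes scanned, 1672 had CCATTTC, 2083 had CATTTCA and 1118 had GAAGAGC in the 3′ UTR.

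**Figure D2:**
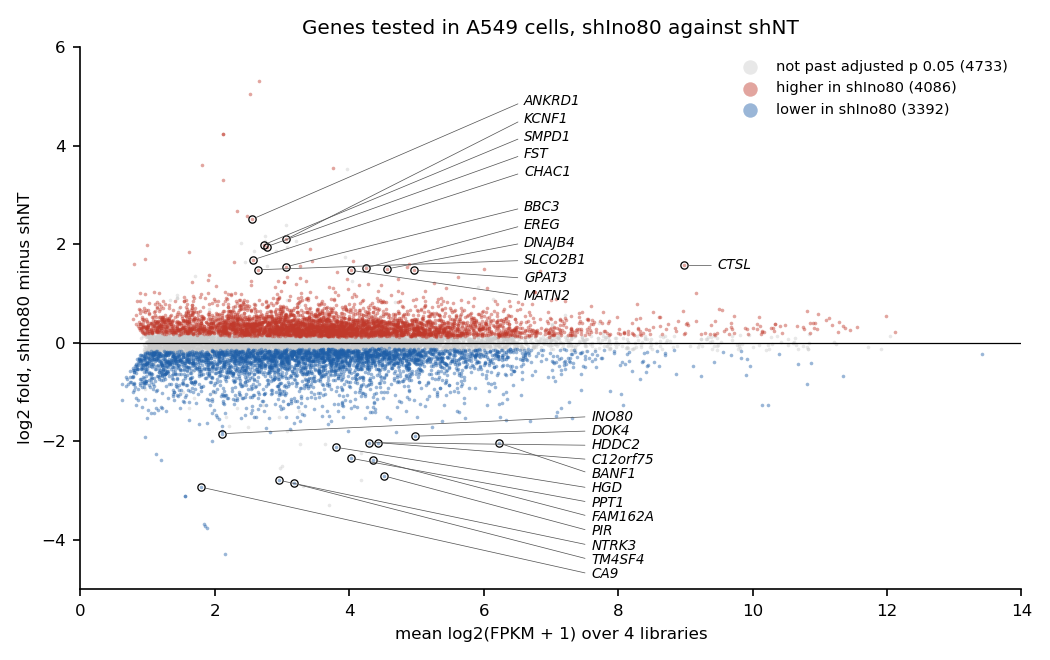
Log2 fold, shIno80 minus shNT, of each of the 12211 tested genes against its mean log2(FPKM + 1) over the 4 libraries. Red marks the 4086 genes that were higher, blue the 3392 that were lower and grey the 4733 that did not pass the adjusted p of 0.05. The 12 largest rises and 12 largest falls by the rule for named genes are circled, and points beyond them are short RNA or genes outside that rule.

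Targets of the tumour suppressor p53 rose as a list. Of 32 tested, 27 rose and 3 fell (camera adjusted p = 1.60e-05, and adjusted p = 0.922 with an estimated correlation). BBC3 led, followed by the antiproliferative gene BTG2 (5.15 ± 0.24 to 14.2 ± 0.222 FPKM), the nuclease gene AEN (22.5 to 42.4 FPKM) and the death receptor FAS (6.31 to 12.3 FPKM). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21 and is among the first 4 of the senescence list, rose from 39.9 to 63.2 FPKM. BBC3, BTG2 and FAS had GAAGAGC, a sequence described below, in the 3′ UTR, and without genes with it the list had an adjusted p of 0.000429. Among ATF4 targets and genes of the unfolded protein response, 19 of 32 rose and 6 fell (adjusted p = 0.0158, and adjusted p = 0.922 with an estimated correlation). They included CHAC1, the stress transcription factor gene DDIT3 (5.62 to 14.7 FPKM), asparagine synthetase ASNS (36.3 to 67.5 FPKM) and HERPUD1 (14.5 to 28.0 FPKM), a protein of the degradation machinery of the endoplasmic reticulum. With a minimum mean of 5 FPKM the list had an adjusted p of 0.051. Of 32 autophagy and lysosome genes, 20 rose and 5 fell (adjusted p = 0.0181, and adjusted p = 0.922 with an estimated correlation). After CTSL came the autophagy kinases ULK1 (15.6 to 24.4 FPKM) and ULK2 (6.21 to 9.80 FPKM), both with GAAGAGC in the 3′ UTR, and ATP6V0D1 (30.8 to 41.6 FPKM), a subunit of the proton pump. Of 53 cytosolic ribosomal protein genes, 33 rose and 3 fell (adjusted p = 0.000639, and adjusted p = 0.922 with an estimated correlation). The median log2 fold was 0.25, and RPSA, RPS12, RPS23 and RPLP0 rose by log2 0.55, 0.64, 0.52 and 0.58. Under the other scalings of the libraries the median log2 fold of this list lay between 0.16 and 0.25.

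Lipid synthesis genes fell. Of 25 genes of cholesterol synthesis and uptake, 18 fell and 1 rose (adjusted p = 1.21e-05, and adjusted p = 0.922 with an estimated correlation). MSMO1 and HMGCS1, which encode enzymes of the pathway, fell from 30.7 ± 2.80 to 13.4 ± 0.341 and from 33.5 to 19.3 FPKM. STARD4, a sterol carrier, fell from 7.95 to 4.27 FPKM. MSMO1 and STARD4 were among the 8 of these 25 genes with CCATTTC or CATTTCA in the 3′ UTR. Without genes with either heptamer the list kept 17 members and had a camera adjusted p of 5.86e-05. Of 17 fatty acid synthesis genes, 11 fell and 2 rose (adjusted p = 0.00226, and adjusted p = 0.922 with an estimated correlation). The desaturases FADS2, FADS1 and SCD fell from 222.9 ± 8.99 to 88.5 ± 0.856, from 134.8 to 64.1 and from 374.9 to 182.9 FPKM, and ATP citrate lyase ACLY fell by 0.63 on the log2 scale. FADS1 had the octamer CCATTTCA.

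The list of glycolysis and hypoxia genes had 20 falls and 3 rises among 35 (adjusted p = 0.000309, and adjusted p = 0.922 with an estimated correlation). Enzymes of the glycolytic pathway itself, named here after their values were seen, were divided. The 12 that did not pass included LDHA, GAPDH, ENO1 and PKM with adjusted p of 0.117, 0.151, 0.253 and 0.451. ALDOC, PFKM, ENO2 and PGK1 fell, with log2 folds of -0.78, -0.31, -0.31 and -0.39, and HK1 rose by log2 0.15. Besides CA9, the carbonic anhydrase CA12 fell from 328 ± 17.6 to 166.5 ± 0.88 FPKM, the vasoactive peptide gene ADM from 18.47 to 11.97 FPKM, and PFKFB3, a regulator of glycolytic flux, from 74.2 to 54.1 FPKM. CA12 had CATTTCA and PFKFB3 had CCATTTC in the 3′ UTR. The list of nuclear-encoded oxidative phosphorylation genes had 11 rises and 18 falls among 44 and did not pass (adjusted p = 0.155). Without shNT replicate 1 it passed as lower (adjusted p = 0.0365), as it did under quantile normalization (adjusted p = 0.0236). COX7C rose from 402 to 806 FPKM in that list, whereas NDUFA9 and ATP5PF fell by 0.72 and 0.54 on the log2 scale.

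Of 24 epithelial genes, 19 fell and 4 rose (adjusted p = 0.000369, and adjusted p = 0.922 with an estimated correlation). The keratins KRT8 and KRT18, which pair in the filaments of simple epithelia, fell together from 1859 ± 70.8 to 769 ± 4.98 FPKM and from 1743 ± 83.8 to 724 ± 4.96 FPKM. E-cadherin CDH1 fell from 14.2 to 6.64 FPKM and plakoglobin JUP from 115.9 to 63.7 FPKM. KRT8, KRT18 and CDH1 had no match to CCATTTC or CATTTCA, and JUP had no 3′ UTR sequence to search. Both keratin genes have processed pseudogenes whose reads these values may share. Mesenchymal and TGF-beta genes went both ways, with 15 of 28 rising and 10 falling (adjusted p = 0.663). CD44 fell from 113.3 to 56.3 FPKM and CALD1 from 44.4 to 28.1 FPKM, and TIMP1 rose by log2 0.56. Of 28 extracellular matrix genes, 9 rose and 12 fell (adjusted p = 0.512). AGRN, VCAN and COL4A1 fell by 1.18, 1.13 and 1.07 on the log2 scale and COL4A6 rose by log2 0.62. The median of that list was 0.003 and the mean -0.13. Of 8 tested genes of the alveolar and airway lineages, 5 fell and 1 rose (adjusted p = 0.0403, and adjusted p = 0.922 with an estimated correlation). CAV1 and LPCAT1, both with the octamer CCATTTCA, fell from 54.9 to 28.7 and from 17.67 to 10.98 FPKM. The mucin MUC5B fell from 4.06 ± 1.02 to 1.15 ± 0.116 FPKM and the transcription factor GATA6 from 1.13 to 0.65 FPKM. Without genes with CCATTTC or CATTTCA the list kept 5 members and had an adjusted p of 0.0605, and without genes with GAAGAGC, described below, it had 0.104. It had 0.0669 with no filter on low values and 0.0519 when the transcript with the highest value stood for each gene.

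Of 40 mitosis and G2/M genes, 23 fell and 1 rose (adjusted p = 0.000639, and adjusted p = 0.922 with an estimated correlation), at a median log2 fold of -0.18. The checkpoint genes MAD2L1 and BUB3 fell from 52.2 ± 1.07 to 26.8 ± 0.51 and from 98.1 to 62.7 FPKM, the spindle gene HMMR from 33.4 to 18.9 FPKM, and topoisomerase TOP2A from 162.8 to 116.6 FPKM. MAD2L1 had CCATTTC in the 3′ UTR. Of 13 tested histone genes, 11 fell and 0 rose (adjusted p = 0.000309, and adjusted p = 0.922 with an estimated correlation). H2BC12, H2BC5, H2BC11 and H2AC18 fell by 1.42, 1.25, 1.56 and 0.74 on the log2 scale. Histone mRNA mostly lacks a poly(A) tail and clustered copies share sequence, so these values cover the part of histone RNA that the library protocol and the alignment let through. DNA replication and G1/S genes had 19 falls and 6 rises among 40 (adjusted p = 0.0471, and adjusted p = 0.922 with an estimated correlation). MCM2, TK1 and GINS3 fell by 0.81, 0.81 and 0.63 on the log2 scale and cyclin CCNE2 rose from 3.04 to 5.85 FPKM. DNA damage repair genes had 12 falls and 3 rises among 36 (adjusted p = 0.0432, and adjusted p = 0.922 with an estimated correlation), with FANCD2, ATR and TP53BP1 lower and LIG4 higher. The last pair of list calls was lost without shNT replicate 2 (adjusted p = 0.0692 for replication and 0.0566 for repair), without shIno80 replicate 1 (adjusted p = 0.129 and 0.151), with no filter on low values (adjusted p = 0.0669 and 0.0632) and with protein-coding genes alone (adjusted p = 0.0695 and 0.0704). The repair list had 0.0644 without genes with GAAGAGC, and the replication list had 0.0519 when the transcript with the highest value stood for each gene. GINS3 had the octamer CCATTTCA, and without genes with either heptamer the replication list had an adjusted p of 0.106.

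**Figure D3:**
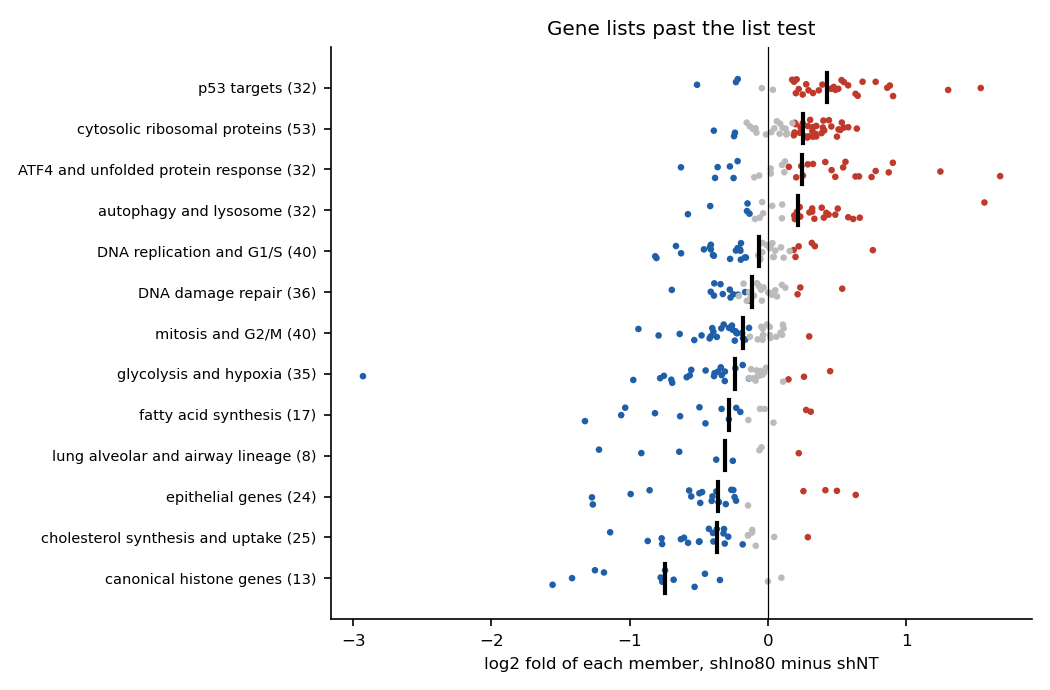
Log2 fold, shIno80 minus shNT, of each tested member of the 13 gene lists that passed camera with a preset correlation, with the number of tested members in brackets. Red members rose, blue members fell, grey members did not pass the adjusted p of 0.05, and the black bar is the median, from 0.43 for p53 targets to -0.74 for histone genes.

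Lung cancer oncogenes did not move together. Of 34 tested, 15 rose and 9 fell (adjusted p = 0.663). The receptor tyrosine kinases FGFR1, AXL and ERBB3 fell from 23.97 to 11.85, from 23.6 to 12.8 and from 6.41 to 2.29 FPKM, and the cell cycle kinase CDK6 rose from 3.01 to 6.07 FPKM. Chosen after its values were seen, MYC rose from 40.6 ± 0.468 to 45.4 ± 0.667 FPKM (log2 fold 0.16, adjusted p = 0.0177). MYC and nucleolar targets had 14 rises and 8 falls among 36 (adjusted p = 0.501), with SRM, PA2G4 and ODC1 higher by log2 0.47 each and NCL lower by the same size. Of 18 tumour suppressors, 6 rose and 4 fell (adjusted p = 0.641). RB1 and NF1, both with the octamer CCATTTCA, fell by 0.83 and 0.53 on the log2 scale, and LATS2 and KEAP1 rose by log2 0.81 and 0.54. KEAP1 had an adjusted p of 0.126 when the transcript with the highest value stood for the gene. NRF2 targets had 16 rises and 9 falls among 34 (adjusted p = 0.641). Against the large fall of PIR and that of the transporter ABCC3 (114.2 to 47.8 FPKM) stood rises of NR0B1 (32.0 to 57.7 FPKM) and haem oxygenase HMOX1 (74.3 to 151.6 FPKM).

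The other lists did not pass either. Interferon response genes had 14 rises and 6 falls among 25 (adjusted p = 0.136, and 0.0459 with a minimum mean of 5 FPKM), led by ISG15 (4.00 to 10.9 FPKM), IRF7, IRF1 and IFI35. NF-kappaB and inflammatory genes had 11 rises and 5 falls among 23 (adjusted p = 0.317), with CSF1, TNFAIP3 and RELB higher and the chemokine CXCL5 lower (128.4 ± 20.8 to 43.9 ± 2.83 FPKM). YAP and TEAD targets had 11 rises and 5 falls among 23 (adjusted p = 0.512), with LATS2 and TEAD4 higher beside ANKRD1 and AXL lower. MAPK feedback and AP-1 genes had 11 rises and 10 falls among 27 (adjusted p = 0.663), led by EREG, AREG, FOSL1 and KLF6, all higher. Senescence-associated genes had 7 rises and 2 falls among 15 (adjusted p = 0.31), with TIMP2 (28.5 to 62.3 FPKM) first. Apoptosis regulators had 11 rises and 7 falls among 26 (adjusted p = 0.641), with BBC3 and MCL1 higher and DIABLO and BCL2L1 lower. Heat shock genes had 4 rises and 6 falls among 16 (adjusted p = 0.852), with DNAJB4 and DNAJA1 higher and HSPB1 and HSPB8 lower. That list had a median log2 fold of -0.007 and a mean of 0.06. Of 32 other chromatin remodelling genes, 9 rose and 10 fell (adjusted p = 0.641), with SMARCA1, CHD3 and HELLS lower and SMARCD1 higher. Polycomb, heterochromatin and DNA methylation factors had 6 rises and 6 falls among 23 (adjusted p = 0.903). CBX5 was lower and CBX7, CBX2 and TRIM28 were higher, the last with an adjusted p of 0.0685 without shIno80 replicate 1. The median of this list was 0.06, whereas its test pointed lower. Mediator, BET and other coactivator genes had 12 rises and 6 falls among 35 (adjusted p = 0.462), with MED8, MED17 and CDK7 higher and MED7 lower. Adjusted over the list alone, the counts of rises and falls were 1 and 21 for cholesterol genes, 35 and 4 for ribosomal protein genes, 20 and 6 for ATF4 and unfolded protein response genes, 12 and 20 for oxidative phosphorylation, 12 and 4 for coactivators, and 16 and 10 each for NRF2 targets, oncogenes and mesenchymal genes. In the remaining 23 lists the counts adjusted over the list alone equalled those over all genes.

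Markers of fibroblasts, leukocytes, endothelium and blood cells were mostly under 1 FPKM, and those of neural cells were mixed. Of 12 fibroblast markers 10 were under 1 FPKM in all 4 libraries, as were 14 of 17 leukocyte, 11 of 12 endothelial and 10 of 12 erythroid and platelet markers. The highest of these by mean over the 4 libraries were COL1A1 (1.54 FPKM in each group), CD68 (8 and 7.65 FPKM), ESAM (1.03 and 1.15 FPKM) and GP1BA (1.60 and 0.99 FPKM). Of 16 neural markers 8 were under 1 FPKM in all 4 libraries, and among the other 8, 3 rose and 3 fell. The most abundant, TUBB3, had 60.1 and 60.6 FPKM, RBFOX3 fell from 8.20 to 4.01 FPKM and SNAP25 rose from 10.8 to 13.99 FPKM. Of 12 genes associated with HEK293 cells and of 12 pluripotency genes, 9 each were under 1 FPKM in all 4 libraries, and the highest were INA (13.98 and 16.06 FPKM) and LIN28B (2.47 and 1.96 FPKM).

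Sequence matches in 3′ UTRs were measured across the transcriptome because many of the largest falls shared one. Of 15440 heptamers searched in 10921 genes, CCATTTC had the lowest z, -16.59, and the overlapping CATTTCA the next, -14.16. The lowest z among permutations of the genes was -5.72 (permutation p = 0.001, the smallest they can give). Genes with the octamer CCATTTCA (499) had a median log2 fold of -0.16, those with CCATTTC alone (1173) -0.07, those with CATTTCA alone (1223) -0.03, those with the shared hexamer alone (1643) 0.04, and those without a match (6383) 0.07. Of genes with the octamer, 50.5% fell and 18.4% rose, against 23.3% and 37.9% of genes without a match. In the other direction GAAGAGC had the highest z, 6.29, where the highest among permutations was 5.35. Genes with the octamer GAAGAGCA (415) had a median log2 fold of 0.13, those with GAAGAGC alone (703) 0.07 and genes without GAAGAGC (9803) 0.02. Of genes with the octamer, 46.0% rose and 21.4% fell, and of those with GAAGAGC alone, 40.1% and 25.3%, against 32.7% and 29.1% of genes without it. With genes that had CCATTTC or CATTTCA left out, 9315 genes were tested, of which 3258 were higher and 2135 lower, and 11 of the 13 lists passed. The 3′ UTR of INO80 had 0 copies of CCATTTCA and its coding sequence had 2.

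**Figure D4:**
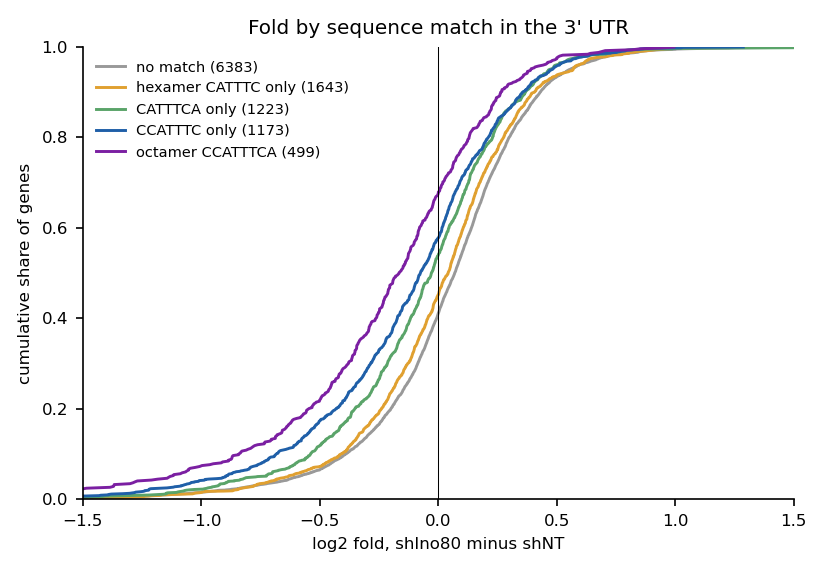
Cumulative share of genes by log2 fold, shIno80 minus shNT, for genes whose 3′ UTR had the octamer CCATTTCA, CCATTTC alone, CATTTCA alone, the hexamer CATTTC alone or no match, with the number of genes in brackets. The curves lie from left to right in that order, with medians from -0.16 for the octamer to 0.07 for no match.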

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

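The tests in this part were chosen after the results they bear on had been seen, except that the predictions for copies per 3′ UTR were written before their values were known, though after the patterns were. Transcripts without a gene name, which entered no comparison, took 0.845 ± 0.049 % of all FPKM with shIno80 and 0.725 ± 0.021 % with shNT (SD, n = 2 each), a difference between groups in values outside the comparisons above.

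The log2 folds of genes with CCATTTC in the 3′ UTR lay lower on the whole than those of genes without it (z -16.59), and a candidate explanation is pairing of the hairpin's guide strand with these 3′ UTRs through its seed, as microRNA do. It predicts a lower fold with more copies, and after removal of trends with length and GC content the mean log2 fold was -0.191 in 337 genes with 2 or more copies and -0.133 in 1335 with 1, a difference of -0.059 (one-sided permutation p = 0.016, adjusted p = 0.016), which any factor that reads this sequence would predict too, whereas base composition of 3′ UTRs would give other heptamers of the same bases a like z, and the lowest was -2.89 among the 132 that share no run of 5 bases with CCATTTC and -5.95 among all 139, at CATTTCC, which holds the hexamer CATTTC. Seed pairing through these heptamers in 3′ UTRs does not account for every large fall either, as far as 1 searched transcript per gene can show. Of the 228 genes lower by log2 1 or more that had a searched 3′ UTR of at least 50 nt, 51.8% had neither heptamer in it. That share was 75.6% among the 4125 such genes not called, so matches were more frequent among the large falls. A response of the genes with CCATTTC to the loss of INO80 stays open and untested, since the labels name 1 hairpin group and give no hairpin sequence. Of 174 genes with the octamer in coding sequence alone, 35.6% fell and 24.7% rose, against 22.3% and 39.5% without a match, so pairing there stays open as well. No trend with length or GC content was removed in this last comparison.

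The log2 folds of genes with GAAGAGC in the 3′ UTR lay slightly higher on the whole than those of genes without it (z 6.29). Among genes with a searched 3′ UTR of at least 50 nt, the sequence was in 34.8% of the 46 higher by log2 1 or more. It was in 12.9% of the 3680 such genes that were higher by any amount. Of such genes not called 9.2% had it, and of those lower by log2 1 or more 8.3%. Seed pairing of the guide strand of the control hairpin, which would lower genes with GAAGAGC with shNT, may explain their higher folds. After removal of the same trends the mean log2 fold was 0.147 in 144 genes with 2 or more copies and 0.057 in 974 with 1, a difference of 0.089 (one-sided permutation p = 0.0083, adjusted p = 0.016), which any factor that reads this sequence would predict too. The highest z of heptamers with the same bases in another order was 2.04 among the 126 that share no run of 5 bases with GAAGAGC. Among all 139 it was 3.11. GAAGAGC had been picked as the highest of all heptamers scanned, so the others had to lie below it. For that reason this comparison cannot settle whether base composition plays a part in the pattern. This pattern is the weaker one, because in 10 random splits of the genes into nearly equal parts GAAGAGC ranked highest in 5 first parts, the heptamer that ranked highest had a z as low as 0.28 in the other part, and the z of GAAGAGC itself ranged from 2.86 to 6.08 over the 20 parts, whereas CCATTTC ranked lowest in all 10 and had a z of -11.26 or lower in the other part. A response to the loss of INO80 stays open and untested here too.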

How the results depend on the processing

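The alternatives that left out genes by 3′ UTR sequence or by protein coding were chosen after seeing the data. Genes higher numbered 3176 to 3887 and genes lower 2868 to 3185 when each library was left out in turn, with 11 to 14 of the lists passing and an INO80 log2 fold of -1.86 to -1.83. In those fits the lone library of a group is assumed to vary like the others. The test against a fold of 1.5 gave 124 higher and 388 lower by its construction. Without genes with CCATTTC or CATTTCA, 2135 genes were lower, with fewer genes tested. Of the list tests, 0 passed with an estimated correlation, 7 with fry for one direction and 31 with fry for either direction, which ask other questions or estimate the correlation from few libraries. The 7 were cholesterol, fatty acid, p53, histone, epithelial and alveolar and airway lineage genes, and YAP and TEAD targets. YAP and TEAD targets (fry adjusted p = 0.0215, higher) had not passed camera, and the remaining lists that passed camera did not pass fry for one direction. The labels state no day or batch shared by same-numbered libraries, and the deviations of same-numbered libraries had a correlation of -0.0016 across genes. With 2 libraries per group this value cannot show whether same-numbered libraries share a culture or batch. With a replicate block 4344 genes were higher and 3565 lower, 13 lists passed, and the INO80 log2 fold was -1.85. YY1, not called, changed sign under median-ratio scaling (-0.003), without shNT replicate 1 (-0.001) and without shIno80 replicate 2 (-0.007), and ranged from -0.007 to 0.069 with each library left out. ACTL6A, not called, reached 0 without shNT replicate 2 and ranged from -0.108 to 0. Of 141 named genes past the threshold, 70 passed the test against a fold of 1.5. Under the other alternatives that tested them, 133 kept their call in every one and 0 reversed. Median-ratio scaling gave 3782 genes higher and 3859 lower, and no filter 3771 and 3690. The median log2 fold of genes with the octamer CCATTTCA minus that of genes without a match was -0.23, and lay between -0.30 (minimum mean of 5 FPKM) and -0.14 (pseudocount of 5 FPKM). Keeping the transcript with the highest value per gene turned 13 of the calls in direction, and quantile normalization turned 1. The cause was not tested. INO80 had a log2 fold of -2.41 with a pseudocount of 0.1 FPKM and -0.95 with 5 FPKM. The absolute depth is unknown, so how far it limits calls of genes near 1 FPKM cannot be stated.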

Other observations

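The tests of lists in this part were chosen after the results had been seen, as were the genes named here that the rule for named genes does not take. Genes of liver-type secreted proteins and enzymes, which A549 cells express, were lower with shIno80. Of 21 tested, 15 fell and 3 rose (adjusted p = 0.000275 over 5 lists chosen after seeing the data, and adjusted p = 0.899 with an estimated correlation). The hepatic transcription factor HNF4A fell from 15.7 ± 0.591 to 5.05 ± 0.0896 FPKM and the receptor FGFR4 from 39.0 ± 1.55 to 13.0 ± 0.573 FPKM. Ceruloplasmin CP fell from 15.8 to 4.54 FPKM, and the apolipoprotein genes APOC1 and APOE from 117 to 49.5 and from 6.754 to 1.404 FPKM. Complement C5, vitronectin VTN and AMBP were the 3 that rose, by log2 0.62, 0.45 and 0.36. Since HGD, FGFR4, APOE and CP had been seen among the falls before the list was written, the list was tested again without them. Of the other 17 genes 11 fell and 3 rose (camera p = 0.00483, and p = 0.381 with an estimated correlation, both unadjusted). A hypothesis that the liver-type genes of these cells fall as a group predicts this direction. In the other lists chosen this way, proteasome subunits had 10 rises and 4 falls among 31, mitochondrial ribosomal proteins 10 and 13 among 46, aminoacyl-tRNA synthetases 11 and 3 among 19, and spliceosome proteins 9 and 7 among 36, with adjusted p of 0.612, 0.638, 0.138 and 0.638.

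Transcripts of a gene went opposite ways in 15 genes with a log2 fold of at least 1 each way, among 17497 transcripts tested singly, and in 3 of these genes the gene sum did not pass the threshold. In TJP1, the tight junction scaffold, a transcript fell from 20.7 and 22.8 to 3.86 and 4.14 FPKM while another rose from 6.76 and 4.51 to 28.85 and 29.02 FPKM. In CA12 the main transcript fell from 307.3 and 331.7 to 111.3 and 108.7 FPKM while a minor one rose from 8.19 and 8.68 to 55.9 and 57.2 FPKM. In RPS24, whose sum was not called, a transcript fell from 199.4 and 191.4 to 18.7 and 13.6 FPKM and another rose from 274.4 and 291.4 to 592 and 611.3 FPKM. These are estimates of how reads shared by the transcripts of a gene divide, and the splice junctions were not analysed here.

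At least 2 copies of CCATTTCA in the coding sequence, as in INO80, occurred in 0.13% of tested genes. The cut of 2 copies was taken from INO80, whose coding sequence has 4671 nt. The share covers coding sequences of every length. Of 215 short RNA tested, 45 rose and 18 fell, but 66 of them were at 0 in one library and at 1 FPKM or more in the other library of the same group, as were 3 other genes. All 16 tested genes listed at 0 in both libraries of a group were such short RNA. Other genes with transcripts of 449 to 3914 nt, the range that holds most ribosomal protein transcripts (7515 genes), had a median log2 fold of 0.04. The 41 other genes above a lower bound on abundance taken from the ribosomal proteins had -0.05, beside 0.25 for the ribosomal protein list. The length range holds most tested genes and the abundance set has no upper bound, so neither is a close match. Whether length or abundance plays a part was not settled. Over 5 groups of tested genes of equal size, from the least to the most expressed in shNT replicate 1, the median log2 fold against shNT replicate 2 was 0.04, 0.04, 0.04, 0.002 and -0.02. The fibroblast marker THY1 fell from 1.98 to 0.21 FPKM while the other markers of that list stayed under 1 FPKM or did not pass.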
